A study of Mus musculus with 6 samples.

How the data were processed

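Liver RNA of 6 ICR mice, 3 labelled control and 3 labelled crizotinib, was sequenced. Per the labels' protocols, RNA was taken with a Qiagen RNeasy kit and 1.3 µg of total RNA per library entered a SMARTer mRNA-seq kit; animals had 7 days of adaptation, 300 mg/kg was the dose, and 3 mice per group were sequenced. The deposited table of 26123 genes held, per the file headers, a read count and an FPKM value (fragments scaled by gene length and library total) for each gene in each library. The counts deposited by the authors were whole numbers that had not been normalized. The FPKM values deposited by the authors equalled the counts scaled by 1 factor per gene and 1 per library. This held to within 0.027 on the log2 scale over 8285 genes with more than 200 counts in every library. The library factor correlated with the library total at r = 0.999, and the gene factor was not checked against gene length. The aligner, counter, annotation and strand setting are not given in the sources used here. Start and end of 23362 of 26060 matched gene identifiers (89.65%) equalled those of GENCODE release M21 on GRCm38, so positions are given on that assembly. Reads of near-identical genes, such as the major urinary protein and Sult2a families, can be assigned to the wrong copy, and reads of overlapping genes to the wrong gene.

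Each library was 1 replicate of its group, with groups taken from the treatment label and never from values. Libraries held between 51123361 and 67947970 counts and between 20327 and 20896 detected genes, and log2 CPM correlated across genes between libraries at r of 0.827 to 0.961; genes are not independent replicates. Depth in controls and crizotinib livers was compared by a two-sided exact permutation test (p = 0.3, n = 3 each). Its smallest possible p is 0.1, so it could not show a difference. Floors and folds against a group at 0 used 3 counts per library and cover counting error only.

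The test, the gene lists, the naming of genes and the first set of other settings were fixed before the data were examined. The plan named limma on log2 FPKM for a table of FPKM alone and edgeR for a table that also held counts, so edgeR was used. Counts were scaled by the trimmed mean of M values. Genes were kept by filterByExpr (minimum count 10, minimum total 15). This left 16492 genes and removed at most 0.0553% of any library's counts. Crizotinib was set against control with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.470. Of 50 gene lists written from general knowledge of mouse liver, 48 were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 48 lists; the other 2, of a technical kind and with no test in the plan, were tested apart without adjustment over lists. Member counts are given over all genes and adjusted over the list alone. Measures of 1 value per library were compared with two-sided exact permutation tests over 20 labelings.

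Genes were named by a rule. It took up to 12 genes per direction with the largest change among those past the threshold, with groups that did not overlap, a mean FPKM of at least 5 in the higher group and no predicted-gene symbol (10 higher and 18 lower genes passed). It also took up to 4 members of each list described with the smallest p, the kinase genes Met, Alk, Ros1 and Mst1r, and 10 further genes, among them Alb, Cyp3a11, Cyp7a1, Cpt1a, Saa1, Cdkn1a, Hmox1, Gdf15 and Ddit3; 1 of the 10 is not reported here. Which lists were described was chosen after the data were seen.

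The steps were tested on simulated counts for the 16492 genes of this comparison, with 3 replicates per group and 50 genes changed at each fold. edgeR recovered 0%, 22%, 60% and 80% of genes changed by 2-, 4-, 8- and 16-fold, with 6.9% false among 87 calls, and DESeq2 (version 1.42.0) recovered 6%, 60%, 82% and 92%, with 25.9% false among 166 calls. The simulated genes varied independently of each other, while the real libraries also differed as wholes. The recovered and false shares therefore need not hold for the real data. Other settings fixed beforehand were DESeq2, DESeq2 size factors in edgeR, no filter on low counts, the replicate number as a block, an estimated correlation for lists, and each library left out in turn. Added after the data were seen were limma on log2(FPKM + 1), limma voom with a quality weight per library, GC and length offsets, removal of mitochondrially encoded genes, and removal of control replicate 1 with crizotinib replicate 3. The FPKM-scale settings fixed beforehand were replaced by the count-scale ones, as the plan stated for a table with counts.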

Results

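Liver transcriptomes of ICR mice, an outbred stock, were compared between 3 animals labelled as controls and 3 animals labelled as given crizotinib, a small-molecule inhibitor of the MET, ALK and ROS1 receptor kinases used in lung cancer. The series describes the experiment as a liver injury model, so the comparison asks which liver transcripts differ after the drug. The stated dose was 300 mg/kg, and tissue was collected 1 week after dosing. The series' own account of the dosing does not say plainly which group received the drug, so the groups follow each sample's treatment label. Messenger RNA was sequenced and counted per gene. The 6 libraries held between 51123361 and 67947970 counts. All levels are CPM, library-scaled counts normalised by the trimmed mean of M values, given as mean ± SD with n = 3, and all fold changes set crizotinib against control. Positions are those of the deposited table, on mouse assembly GRCm38.

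The libraries differed in composition within each group. Mitochondrially encoded genes took 44.5%, 7.47% and 17.6% of the counts of control replicates 1, 2 and 3, and 5.67%, 5.53% and 14.4% of crizotinib replicates 1, 2 and 3, a difference that did not exceed the spread (two-sided exact permutation test p = 0.2, where 0.1 is the smallest p that 3 against 3 allows). The 27 acute-phase genes of a list fixed beforehand took 30.0% and 29.3% of crizotinib replicates 1 and 2 but 4.81% of crizotinib replicate 3, next to 1.18%, 5.22% and 2.41% in the controls (two-sided exact permutation test p = 0.2). Albumin transcripts (Alb) were below every control in all 3 crizotinib libraries, with 1.93 ± 0.758% against 4.73 ± 0.978% of counts (two-sided exact permutation test p = 0.1, n = 3 each). The first principal component of log2 CPM carried 53.3% of the variance and placed crizotinib replicates 1 and 2 at 107 and 95.1, crizotinib replicate 3 at -16.3, and the controls at -103, -28.7 and -54.0.

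**Figure D1:**
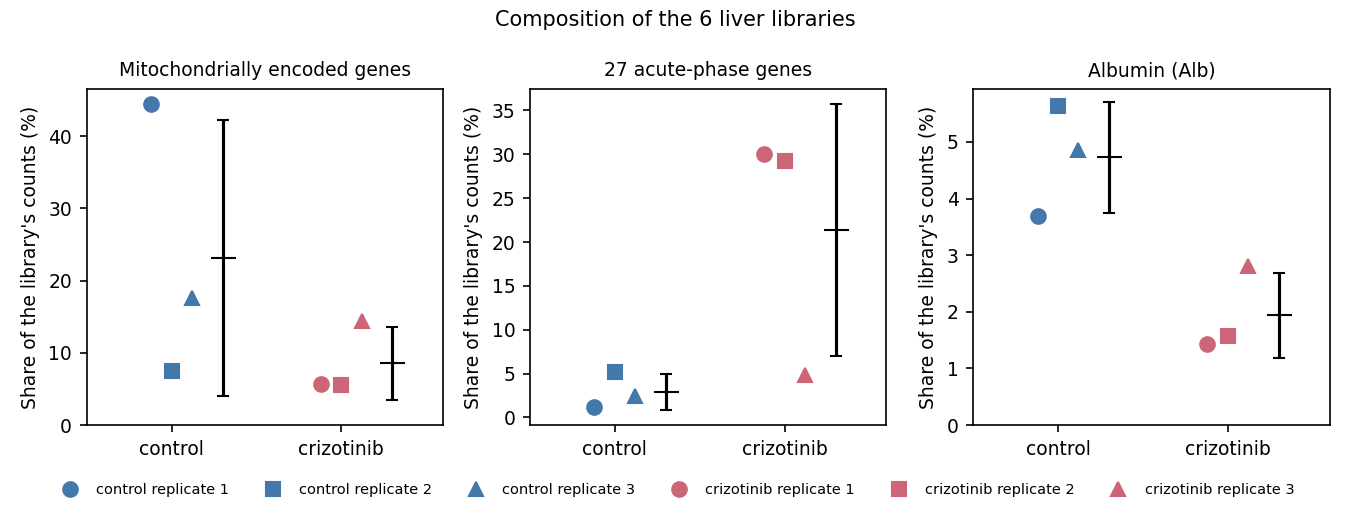
Share of each library's counts, in percent, taken by mitochondrially encoded genes (left), the 27 acute-phase genes (middle) and albumin (right); symbols are single libraries, and the black bars are the group mean ± SD (n = 3). Crizotinib replicate 3 has 4.81% acute-phase counts against 30.0% and 29.3% in the other crizotinib libraries.

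Crizotinib livers had higher transcript levels of the sulfotransferase genes Sult1e1, Sult2a1 and Sult2a2 and of enzymes of the cholesterol pathway, and lower levels of major urinary protein genes, other male-biased liver genes and genes of resident liver macrophages. Of 16492 genes tested, 56 changed, 15 of them higher and 41 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p between 0.00786 and 0.0499). Each of the 56 differed by more than 2-fold and had no overlap between the groups; among all tested genes 3462 (21.0%) had no overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 2525 genes, 1329 higher and 1196 lower. The count of 56 rested on the set of libraries. Without crizotinib replicate 3 it was 1504 (700 higher and 804 lower). It was 3 without control replicate 2, crizotinib replicate 1 or crizotinib replicate 2, and 0 by edgeR without control replicate 1 or control replicate 3, where 1985 and 1705 genes had an unadjusted p under 0.05. DESeq2 on all 6 libraries called 1105 genes, 512 higher and 593 lower. All 56 genes kept their direction in each of these fits, which their lack of overlap between the groups largely fixed in advance. Of the 3 genes called without control replicate 2, crizotinib replicate 1 or crizotinib replicate 2, 2 were among the 56.

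The largest rises among the named genes were those of 3 sulfotransferase genes, whose enzymes add sulfate to steroids and bile acids. The list of conjugation enzymes holds Sult2a1 but not Sult1e1 or Sult2a2, along with glucuronosyl- and glutathione transferases. It was lower, with a median log2 fold change of -0.62 (limma's camera adjusted p = 0.0436, and adjusted p = 0.766 with an estimated correlation). Of its 27 members 1 rose over all genes, Sult2a1, and 2 when adjusted over the list alone, while 21 had a fitted fold change below 0. That call was lost without control replicate 2, control replicate 3, crizotinib replicate 1 or crizotinib replicate 2 (limma's camera adjusted p = 0.113, 0.196, 0.530 and 0.201), and the median was -0.28 without crizotinib replicate 1. It was -1.28 without crizotinib replicate 3, where 2 members rose and 9 fell over all genes. Sult1e1, the estrogen sulfotransferase (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594), rose from 0.720 ± 0.543 to 80.9 ± 46.4 CPM, a log2 fold change of 6.79 ± 0.85 (SE; edgeR adjusted p = 0.0430). Sult2a1 (ENSMUSG00000078798, chromosome 7, 13796246 to 13837409) rose from 0.152 ± 0.0714 to 11.7 ± 9.50 CPM and its paralog Sult2a2 from 0.288 ± 0.307 to 14.2 ± 5.64 CPM; reads of this family can be assigned to the wrong copy, so each value is uncertain. Nnmt, nicotinamide N-methyltransferase (ENSMUSG00000032271, chromosome 9, 48591877 to 48605153), rose from 8.60 ± 2.88 to 302 ± 188 CPM, with 399, 422 and 84.6 CPM in crizotinib replicates 1, 2 and 3. Smaller rises were those of Rcan2 by 2.84, Bcl3, a partner of NF-kappa-B, by 2.26, Tmem98 by 2.11 and Rnd2 by 1.63 on the log2 scale. Rnd2 overlaps Vat1 on the opposite strand, which stood at a log2 fold change of 1.37 (edgeR adjusted p = 0.106), and whether counting used the strand is not given in the sources used here. The same limit holds for Bcl3, Hsd3b5, Folr2, Rcan2, Col14a1 and Cspg5, which overlap genes on the opposite strand.

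**Figure D2:**
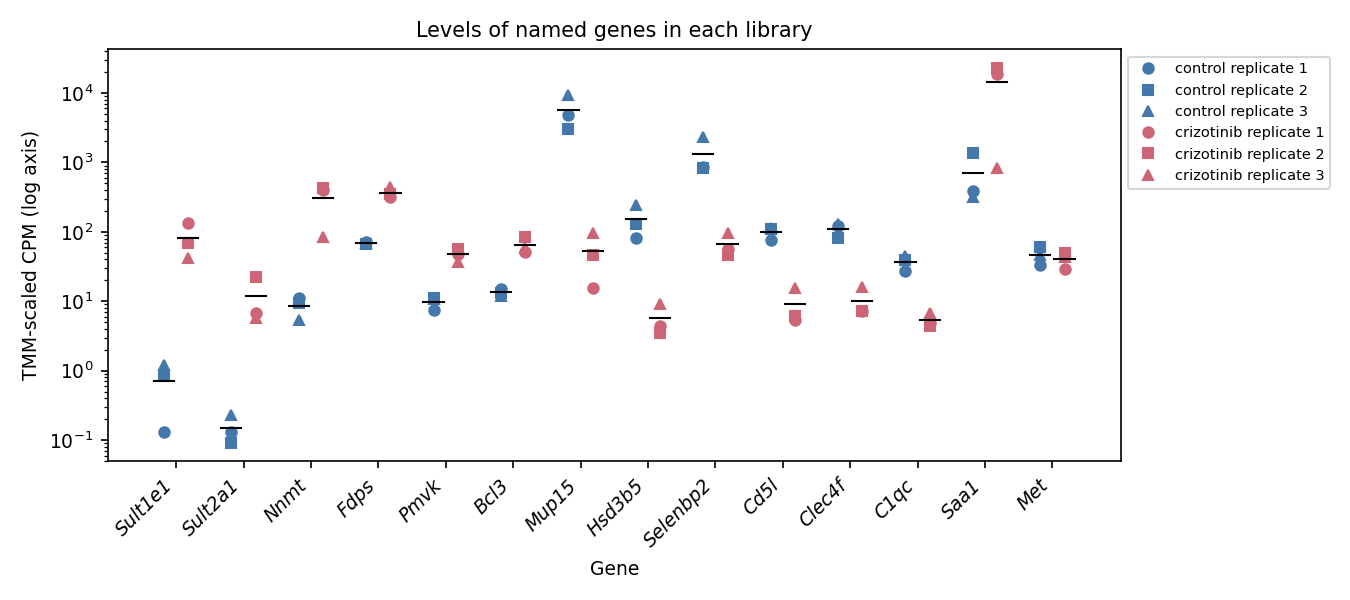
TMM-scaled CPM (log axis) of 14 named genes in each library; blue symbols are controls, red symbols are crizotinib livers, and black lines are group means (n = 3). Sult1e1 lies between 41.8 and 132 CPM in the crizotinib livers and between 0.133 and 1.20 CPM in the controls, while Met and Saa1 have overlapping groups.

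Cholesterol synthesis genes were higher as a group in all 3 crizotinib livers. All 24 listed members had a fitted fold change above 0, with a median log2 fold change of 1.55, or 2.92-fold (limma's camera adjusted p = 1.55e-20; adjusted p = 0.122 with an estimated correlation). Over all genes 2 of the 24 rose, and 17 did when adjusted over the list alone. The count over all genes was 12 without crizotinib replicate 3. Without any one of the other libraries it was 0 by edgeR, with 16 to 18 adjusted over the list alone. Fdps, farnesyl diphosphate synthase (ENSMUSG00000059743, chromosome 3, 89093588 to 89101959), rose from 68.7 ± 2.73 to 368 ± 65.0 CPM, a log2 fold change of 2.42 ± 0.33 (SE; edgeR adjusted p = 0.0431). Pmvk, phosphomevalonate kinase (ENSMUSG00000027952, chromosome 3, 89454541 to 89469013), rose from 9.80 ± 1.93 to 47.2 ± 9.90 CPM. Lss had 30.9 ± 4.18 and 117 ± 30.2 CPM, and Hmgcs1 had 99.4 ± 1.603 and 576 ± 308 CPM, with edgeR adjusted p of 0.0583 and 0.0785. Per library, the list's median deviation from the control mean was 1.46, 1.57 and 1.78 on the log2 scale in crizotinib replicates 1, 2 and 3, and -0.27, 0.04 and 0.11 in control replicates 1, 2 and 3.

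Genes with higher expression in male than in female mouse liver were lower in crizotinib livers. All 29 tested members of the list had a fitted fold change below 0, with a median log2 fold change of -3.17, or 9.02-fold lower (limma's camera adjusted p = 8.45e-35; adjusted p = 0.285 with an estimated correlation). Over all genes 4 of the 29 fell, and 27 did when adjusted over the list alone. The count over all genes was 20 without crizotinib replicate 3, and without any one of the other libraries it was 0 by edgeR, with 22 to 27 adjusted over the list alone. The list holds 9 major urinary protein genes, and its other 20 members had a median of -2.82. Hsd3b5, a steroid dehydrogenase (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252), fell from 152 ± 83.1 to 5.69 ± 3.02 CPM, a log2 fold change of -4.74 ± 0.59 (SE; edgeR adjusted p = 0.0430). Selenbp2 fell from 1337 ± 868 to 66.0 ± 26.2 CPM, Cspg5 from 6.09 ± 2.64 to 0.570 ± 0.230 CPM and Susd4 from 9.16 ± 1.35 to 1.20 ± 0.475 CPM. Among major urinary protein genes outside the list, whose near-identical copies on chromosome 4 share reads and so have uncertain single values, Mup15 fell from 5709 ± 3251 to 52.96 ± 40.7 CPM and Mup9 from 467 ± 87.4 to 32.1 ± 17.8 CPM. The pseudogenes Mup-ps18 and Mup-ps20 had 148 ± 43.2 and 91.3 ± 30.7 CPM in controls and no count in any crizotinib library. Against a floor of 3 counts per library their counts were at least 2559-fold and at least 1578-fold lower. These bounds cover counting error only and not reads assigned to another copy, so they are no least size of a change in transcript. Outside the list, Serpina12, which encodes the adipokine vaspin, fell from 55.5 ± 40.3 to 3.58 ± 0.678 CPM.

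The list of female-biased liver genes was higher as a whole, but its members did not move together. Of 26 tested members 4 rose over all genes and 6 when adjusted over the list alone, and the median log2 fold change was 0.59 (limma's camera adjusted p = 0.000256; adjusted p = 0.509 with an estimated correlation). The 4 were Sult1e1, Sult2a1, Sult2a2 and Cyp17a1, a steroid 17-alpha-hydroxylase that rose from 0.858 ± 0.572 to 10.7 ± 2.26 CPM. The list's median deviation was 2.26 in crizotinib replicate 3 but -0.96 and -0.31 in crizotinib replicates 1 and 2, within or below the controls' range of -0.87 to 0.41. Without crizotinib replicate 3 the list's median was -0.97 (limma's camera adjusted p = 0.818), with 6 members higher and 3 lower over all genes; without control replicate 1, control replicate 2 and crizotinib replicate 2 the median was 1.31, 1.25 and 1.11, and without control replicate 3 it was 0.20. Without any one library other than crizotinib replicate 3 no member passed edgeR's test over all genes, and 5 to 8 did when adjusted over the list alone.

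Markers of Kupffer cells, the resident macrophages of the liver, were lower in all 3 crizotinib livers. Of 15 tested markers 14 had a fitted fold change below 0, and the median log2 fold change was -2.69, or 6.45-fold lower (limma's camera adjusted p = 5.58e-32; adjusted p = 0.107 with an estimated correlation). Over all genes 7 of the 15 fell and 14 did when adjusted over the list alone. Without crizotinib replicate 3 the count over all genes was 12, and without any one of the other libraries it was 0 by edgeR, with 13 or 14 adjusted over the list alone. Clec4f, a lectin found on Kupffer cells (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187), fell from 111 ± 24.3 to 10.1 ± 5.03 CPM, a log2 fold change of -3.45 ± 0.43 (SE; edgeR adjusted p = 0.0430). Cd5l, a secreted macrophage protein, fell by 3.47 on the log2 scale, to 5.35, 6.03 and 15.6 CPM from 99.9 ± 21.0 CPM. The complement genes C1qb and C1qc fell from 38.0 ± 4.40 to 6.40 ± 0.645 and from 37.1 ± 8.88 to 5.38 ± 1.32 CPM, and Folr2 from 6.31 ± 2.53 to 0.306 ± 0.198 CPM. Cd68 and Csf1r, named after their values were seen, were the remaining members that fell, with log2 fold changes of -2.69 and -2.54. The list's median deviation was -2.75, -3.41 and -2.40 in crizotinib replicates 1, 2 and 3.

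**Figure D3:**
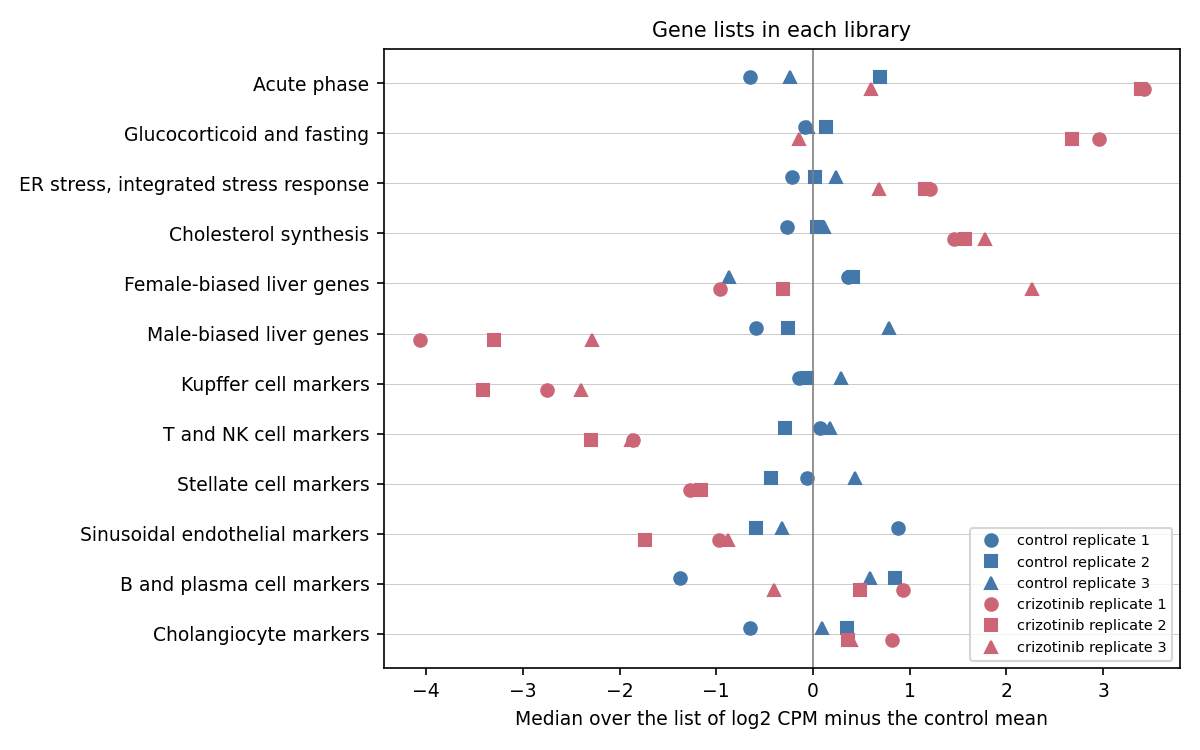
Median over each gene list of log2 CPM minus the control mean, one symbol per library (blue, controls; red, crizotinib). Kupffer cell markers lie at -2.75, -3.41 and -2.40 and cholesterol synthesis genes at 1.46, 1.57 and 1.78 in the crizotinib livers, while acute-phase genes lie at 3.42, 3.39 and 0.60.

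Lists of T and NK, stellate, sinusoidal endothelial, mesothelial, platelet and pancreas markers were also called lower, while B cell and cholangiocyte lists were not called. T and NK cell markers had a median log2 fold change of -2.24 (limma's camera adjusted p = 1.28e-11; adjusted p = 0.101 with an estimated correlation), with no member past edgeR's test over all genes, 10 of 16 when adjusted over the list alone and 12 at an unadjusted p under 0.05. Adjusted over the list alone, 5 passed without control replicate 1 or control replicate 3 and 4 without crizotinib replicate 2, and without crizotinib replicate 3 there were 3 over all genes. Ccl5, a T cell chemokine, had 2.88 ± 1.49 and 0.473 ± 0.0423 CPM, and Il2rb had 2.19 ± 0.283 and 0.533 ± 0.172 CPM in control and crizotinib livers. Hepatic stellate cell markers had a median of -1.33 (limma's camera adjusted p = 6.81e-09; adjusted p = 0.298 with an estimated correlation); none of 17 passed edgeR's test over all genes, 8 did when adjusted over the list alone and 10 were lower at an unadjusted p under 0.05, while 5 passed over all genes without crizotinib replicate 3. Colec11 came closest, at 20.6 ± 3.38 and 2.41 ± 1.54 CPM (edgeR adjusted p = 0.0502). Sinusoidal endothelial markers had a median of -1.34 (limma's camera adjusted p = 1.96e-06; adjusted p = 0.461 with an estimated correlation), with 0 of 17 past edgeR's test over all genes, 3 when adjusted over the list alone and 10 at an unadjusted p under 0.05. Adjusted over the list alone, 10 passed without control replicate 2 and 0 without crizotinib replicate 2; the median was -0.77 without control replicate 1, and 2 passed over all genes without crizotinib replicate 3. B cell and cholangiocyte lists had medians of 0.15 and 0.42 (limma's camera adjusted p = 0.420 and 0.172). The B cell median was -0.35 without control replicate 1, 0.46 without control replicate 2, 0.41 without crizotinib replicate 3 and -0.16 without crizotinib replicate 1. The cholangiocyte list was called without control replicate 2 (limma's camera adjusted p = 0.0482), and its median was 0.04 without control replicate 1 and 0.15 without crizotinib replicate 1.

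Mesothelial markers had a median of -2.61 over 3 tested members (limma's camera adjusted p = 0.000513; adjusted p = 0.295 with an estimated correlation), with 0 past edgeR's test over all genes, 3 lower when adjusted over the list alone and 3 at an unadjusted p under 0.05. Their median deviation was -1.71, -2.11 and -2.81 in crizotinib replicates 1, 2 and 3. Platelet markers had a median of -0.85 over 5 tested members (limma's camera adjusted p = 0.0412; adjusted p = 0.522 with an estimated correlation). That call was lost without control replicate 3 and without crizotinib replicate 3 (limma's camera adjusted p = 0.106 and 0.148), and the median was -1.35 without crizotinib replicate 1. The pancreas list, kept as a sign of other tissue in the samples, had 3 tested of 16 members and a median of -2.64 (limma's camera adjusted p = 0.00203; adjusted p = 0.296 with an estimated correlation), with 0 past edgeR's test over all genes, 2 lower when adjusted over the list alone and 1 fitted above 0. Its median deviation was -3.66, -2.42 and -1.99 in crizotinib replicates 1, 2 and 3. The call was lost without crizotinib replicate 3 (limma's camera adjusted p = 0.0744), where 2 fell over all genes.

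Acute-phase genes, which the liver secretes in inflammation, were higher as a group, largely in crizotinib replicates 1 and 2. All 27 members had a fitted fold change above 0 and the median log2 fold change was 2.83, or 7.13-fold (limma's camera adjusted p = 6.87e-20; adjusted p = 0.445 with an estimated correlation). None of the 27 passed edgeR's test over all genes, while 24 did when adjusted over the list alone and 24 had an unadjusted p under 0.05. Without crizotinib replicate 3 the count over all genes was 22. Adjusted over the list alone it was 3 without control replicate 1, 2 without control replicate 3 and 12 without crizotinib replicate 2. The list's median deviation was 3.42, 3.39 and 0.60 in crizotinib replicates 1, 2 and 3, against -0.65, 0.69 and -0.24 in the controls. Saa1, serum amyloid A, had 18883, 22824 and 833 CPM in crizotinib replicates 1, 2 and 3 and 384, 1378 and 316 CPM in control replicates 1, 2 and 3 (log2 fold change 4.36 ± 1.27 SE, edgeR adjusted p = 0.184). Socs3, a feedback inhibitor of cytokine signalling, had 148, 160 and 33.7 CPM in the crizotinib livers against 10.7 ± 2.25 CPM in controls (edgeR adjusted p = 0.0694). Lcn2, lipocalin 2, had 8448, 10070 and 580 CPM against 204 ± 173 CPM.

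Glucocorticoid and fasting response genes followed the same libraries. Of 20 tested members 1 rose over all genes, Sult1e1, and 14 when adjusted over the list alone, with a median log2 fold change of 2.48 (limma's camera adjusted p = 2.55e-09; adjusted p = 0.461 with an estimated correlation). The median deviation was 2.96, 2.68 and -0.14 in crizotinib replicates 1, 2 and 3. Immediate-early genes, a list kept as a sign of tissue handling and not among the 48, were also higher, with deviations of 1.75, 1.12 and 0.18 in crizotinib replicates 1, 2 and 3. Their median log2 fold change was 1.19, with 16 of 18 fitted above 0 (limma's camera unadjusted p = 2.68e-05; unadjusted p = 0.204 with an estimated correlation, tests not in the plan). None of the 18 passed edgeR's test over all genes, 6 did when adjusted over the list alone and 9 had an unadjusted p under 0.05. With single libraries left out the median lay between 0.70 and 1.49; 8 rose over all genes without crizotinib replicate 3, and adjusted over the list alone 0 passed without any one control or without crizotinib replicate 1. Over all genes 15 glucocorticoid and fasting members rose and 1 fell without crizotinib replicate 3. Without any one of the other libraries none passed edgeR's test over all genes, and the count adjusted over the list alone was 1 without any one control and 7 without crizotinib replicate 1 or crizotinib replicate 2. Tat, tyrosine aminotransferase, had 8708, 5717 and 904 CPM in crizotinib replicates 1, 2 and 3 against 515 ± 20.5 CPM in controls. Genes of the endoplasmic reticulum and integrated stress responses had a median of 1.09 (limma's camera adjusted p = 3.39e-09; adjusted p = 0.391 with an estimated correlation), with 0 of 29 past edgeR's test over all genes, 15 when adjusted over the list alone and 16 at an unadjusted p under 0.05. Adjusted over the list alone it was 0 by edgeR without any one library other than crizotinib replicate 3, and without crizotinib replicate 3 it was 8 over all genes. Creld2, a chaperone-like protein of this compartment, had 19.3 ± 4.52 and 53.5 ± 12.6 CPM. Ddit3, which encodes the stress factor CHOP, had 7.81 ± 1.85 and 6.52 ± 2.72 CPM (edgeR adjusted p = 0.773).

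Proliferation genes had a median log2 fold change of -1.14 (limma's camera adjusted p = 5.76e-06; adjusted p = 0.509 with an estimated correlation), with 0 of 31 past edgeR's test over all genes or over the list alone and 10 lower at an unadjusted p under 0.05. Adjusted over the list alone 11 passed without control replicate 2, and the median was -0.70 without control replicate 1. Top2a had 4.40 ± 1.68 and 1.45 ± 0.323 CPM. Mcm10, a replication factor outside that list, fell from 59.5 ± 27.1 to 7.26 ± 1.64 CPM. Its control level lay far above that of Top2a, and whether its fall goes with proliferation was not tested. Mitochondrially encoded genes had a median of -1.94 (limma's camera adjusted p = 0.000496; adjusted p = 0.632 with an estimated correlation), and without control replicate 1 it was -0.59 (limma's camera adjusted p = 0.149). Erythroid genes had a median of -1.70 (limma's camera adjusted p = 0.0104; adjusted p = 0.509 with an estimated correlation), with deviations of -3.27, -2.41 and -0.54 in crizotinib replicates 1, 2 and 3 and a median of -3.04 without crizotinib replicate 3. In all, 23 of 48 lists were called, 8 higher and 15 lower, and with an estimated correlation none was (7 had an unadjusted p under 0.05 by limma's camera). At the preset correlation, splits of the 6 libraries that mix the groups called 12 to 20 lists.

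No kinase gene among those that crizotinib inhibits passed the test for a change in transcript level. The list of 7 tested genes of these kinases and their ligands was not called (median -0.54, limma's camera adjusted p = 0.122), with 0 past edgeR's test over all genes, 1 lower when adjusted over the list alone and 2 lower at an unadjusted p under 0.05. Axl, a related receptor kinase, had 24.0 ± 1.76 and 12.7 ± 0.823 CPM (edgeR adjusted p = 0.143). Met, which encodes the hepatocyte growth factor receptor (ENSMUSG00000009376, chromosome 6, 17463800 to 17573980), had 46.6 ± 13.4 CPM in controls and 40.4 ± 10.6 CPM in crizotinib livers, a log2 fold change of -0.20 ± 0.33 (SE; edgeR adjusted p = 0.799). Mst1r had 0.665 ± 0.0638 and 0.685 ± 0.294 CPM, Alk had 30 counts over all 6 libraries and was not tested, and Ros1 was not analysed here. The list of drug-metabolising genes under CAR and PXR control was not called (limma's camera adjusted p = 0.754); its mean log2 fold change was 0.30 and its median -0.00082, on the other side of 0 from its mean and test. Its member Cyp2b10, a drug-inducible cytochrome P450, had 7.25 ± 2.68 and 65.1 ± 41.6 CPM (edgeR adjusted p = 0.0630), and Cyp3a11 had 2065 ± 836 and 3722 ± 2248 CPM (edgeR adjusted p = 0.563). Without crizotinib replicate 3 that list's median was -0.72 (limma's camera adjusted p = 0.0168).

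Bile acid synthesis genes had a median log2 fold change of -0.47 and were not called (limma's camera adjusted p = 0.0818). The list was called without control replicate 1 and without crizotinib replicate 3 (limma's camera adjusted p = 0.0111 and 0.0253), with medians of -0.54 and -0.75, and with no filter on low counts (limma's camera adjusted p = 0.0454). Its median was -0.31 without control replicate 2, -0.24 without control replicate 3, -0.11 without crizotinib replicate 1 and -0.30 without crizotinib replicate 2. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 5.69, 3.02 and 253 CPM in crizotinib replicates 1, 2 and 3 against 127 ± 44.2 CPM in controls (edgeR adjusted p = 0.872). Cyp8b1, which makes cholic acid, had 179 ± 68.2 and 42.4 ± 35.3 CPM (edgeR adjusted p = 0.190). Igfbp3, a carrier of insulin-like growth factors, fell from 39.6 ± 10.9 to 8.13 ± 2.10 CPM (edgeR adjusted p = 0.0447), within a growth hormone list that was not called (limma's camera adjusted p = 0.129) but was without control replicate 1 (limma's camera adjusted p = 0.0404). Cdkn1a, the p21 cell cycle inhibitor, had 96.7, 155 and 6.80 CPM and Hmox1, heme oxygenase 1, had 234, 84.1 and 12.9 CPM in crizotinib replicates 1, 2 and 3, against 4.70 ± 1.95 and 17.6 ± 5.49 CPM in controls (edgeR adjusted p = 0.142 and 0.215). Gdf15 had 4.08 ± 1.95 and 8.74 ± 4.86 CPM and Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, had 204 ± 108 and 220 ± 126 CPM (edgeR adjusted p = 0.342 and 0.938).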

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

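The tests on FPKM, with voom weights, with GC and length offsets, without mitochondrially encoded genes and without control 1 and crizotinib 3 together were chosen after the results were seen; the others were planned. All 56 genes kept their direction in every setting in which they were tested. As their groups did not overlap, this was largely fixed in advance and is no measure of stability. The count was 61 with DESeq2 size factors, 56 without a filter, 60 with GC and length offsets and 61 without mitochondrially encoded genes. It was 1105 (512 higher, 593 lower) with DESeq2, 109 (37 and 72) with limma on FPKM, where the median of all genes lay at 0.147, 3217 (1540 and 1677) with voom weights, and 1718 (796 and 922) without control 1 and crizotinib 3 together. With single libraries left out it ranged from 0 to 1504, with 0 to 700 higher and 0 to 804 lower; the cause of these moves was not tested. Called lists numbered 17 to 26, and 0 with an estimated correlation (7 at an unadjusted p under 0.05 by limma's camera). Directions reversed for the interferon list (-2.16 to 0.39 with single libraries left out) and the heat shock list (-0.46 to 0.85, with voom weights -0.37, without control 1 and crizotinib 3 together -0.58). The female-biased list had a median of -0.97 without crizotinib replicate 3 and up to 1.31 with other single libraries left out, while the direction of its test stayed higher. Directions also reversed for the log2 fold change of Mst1r (-0.20 to 0.36, voom -0.0964, without control 1 and crizotinib 3 together -0.28), the log2 fold change of Cyp3a11 (voom -0.13), the log2 fold change of Cyp7a1 (-4.89 to 0.0354) and the log2 fold change of Cpt1a (-0.41 to 0.56). The cause was not tested. Planned pseudocount, scaling, filter and variance settings for FPKM were not run, since counts took their place, and DESeq2 has no camera test.

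With the replicate block edgeR called 0 genes (0 higher, 0 lower; lowest adjusted p 0.0862), against 2068 at an unadjusted p under 0.05, and 21 lists. The bile acid synthesis list was then called (limma's camera adjusted p = 0.0197), as it was without a filter, on FPKM, with voom weights and without control 1 and crizotinib 3 together (limma's camera adjusted p = 0.0454, 0.0223, 0.0484 and 0.00556). The log2 fold change of Mst1r was then -0.0526. Libraries with the same number correlated at -0.149, 0.164 and -0.0902 in their deviations from the group means, so the numbers were not taken to pair animals.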

Other observations

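The tests of KEGG pathways, those with GC and length offsets or without control 1 and crizotinib 3 together, and the tests of a wrong label, a mixture, dilution, blood, shared reads and female animals were chosen only after the results were seen. Among lists not described above, genes of hepatocytes around the central vein had a median log2 fold change of -0.42 (limma's camera adjusted p = 0.0336; adjusted p = 0.752 with an estimated correlation), with 0 of 20 past edgeR's test over all genes or over the list alone and 1 lower at an unadjusted p under 0.05. The call was lost without control replicate 2, control replicate 3, crizotinib replicate 1 or crizotinib replicate 2 (adjusted p = 0.0517, 0.106, 0.342 and 0.125), and without crizotinib replicate 3 the median was -1.56, with 9 of 20 lower over all genes. Neutrophil markers had a median of 1.602 (limma's camera adjusted p = 0.0336; adjusted p = 0.632 with an estimated correlation), with deviations of 2.55, 1.94 and -0.03 in crizotinib replicates 1, 2 and 3. That call was lost without crizotinib replicate 1 (adjusted p = 0.210), and the median was 2.62 without control replicate 2 and 2.49 without crizotinib replicate 3. Col14a1, a fibril-associated collagen, fell from 33.8 ± 15.7 to 4.42 ± 1.21 CPM (edgeR adjusted p = 0.0431), while the matrix list it belongs to was not called (limma's camera adjusted p = 0.443) except without crizotinib replicate 3, alone or together with control 1 (adjusted p = 0.0191 and 0.0127). NRF2 and p53 target lists were not called (limma's camera adjusted p = 0.882 and 0.924), and in both the median, -0.03 and -0.17, lay on the other side of 0 from the mean and the test. Leaving out crizotinib replicate 3 gave the NRF2 list a median of -0.75 (adjusted p = 0.0679), with 2 members higher and 7 lower over all genes and 3 and 10 when adjusted over the list alone, and the p53 list 3 members higher and 1 lower over all genes. The NRF2 list was called without control 1 and crizotinib 3 together (adjusted p = 0.026).

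Over 303 KEGG pathways with 10 to 300 tested members, 22 were called by limma's camera, 8 higher and 14 lower, and 0 with an estimated correlation. Terpenoid backbone biosynthesis had a median of 0.88 over 21 members (limma's camera adjusted p = 3.07e-06; adjusted p = 0.917 with an estimated correlation) and steroid biosynthesis 1.19 over 16 members. Steroid hormone biosynthesis had a median of -0.69 over 69 members (limma's camera adjusted p = 0.0049; all 3 had an adjusted p = 0.917 with an estimated correlation), of which 3 rose and 1 fell. Xist had 0.199, 3.79 and 5.57 CPM in control replicates 1, 2 and 3 and 14.3, 14.4 and 6.93 CPM in crizotinib replicates 1, 2 and 3, and the Y-linked Ddx3y lay between 31.0 and 55.6 CPM in all 6 libraries.

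The 3 livers against 3 make 10 splits, too few for a share under 0.05. The real split gave 56 genes and the highest other split 1, so 1 split reached 56. At an unadjusted p under 0.05 the real split gave 2525 genes and the split of control replicates 1 and 3 with crizotinib replicate 3 against the rest gave 2862, so the libraries also differ along a line that puts crizotinib replicate 3 with control replicates 1 and 3, and control replicate 2 with crizotinib replicates 1 and 2. For lists the real split gave 23 and the other splits 12 to 20, so 1 split reached 23. At the preset correlation many lists were thus also called in splits that mix the groups. A list's call there does little by itself to set the real split apart.

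Crizotinib replicate 3 lacked most of the acute-phase rise. Its Kupffer cell median was -2.397, below every control by more than their range of 0.4345. That goes against a control library under a wrong label. The list was picked, however, after its fall in all 3 crizotinib libraries was seen, so this outcome was in part fixed by the choice. Over genes chosen without crizotinib replicate 3 its position was 0.213, where 0 is control and 1 crizotinib. That lay within the positions of the controls left out the same way (0.0769, 0.34 and 0.0524). Crizotinib replicates 1 and 2 lay at 0.975 and 1.1, but over genes chosen in fits that held crizotinib replicate 3. The positions are therefore not like for like and do not decide on a wrong label. Cholesterol synthesis genes, at 1.78 in crizotinib replicate 3, lay outside the controls' -0.27 to 0.11. Male-biased genes, at -2.29, lay outside the controls' -0.59 to 0.79. Both argue against a control library, but these lists too were picked after the data were seen, so a wrong label is not ruled out. One mixture of treated and control RNA is argued against by the share of treated RNA it would need, 4.482% over acute-phase genes (interquartile range 0.793% to 8.63%) and 93.7% over Kupffer cell genes (90.0% to 99.1%). The same shares were 94.5% over male-biased genes (84.6% to 97.5%) and 103% over cholesterol synthesis genes (72.7% to 207%). They measure a mixture on the linear scale and not the strength of a response, so they do not decide on a weaker drug response. Median log2 deviations in crizotinib replicates 1, 2 and 3 were -4.06, -3.29 and -2.29 over male-biased genes. They were -2.75, -3.41 and -2.40 over Kupffer cell markers, and 1.46, 1.57 and 1.78 over cholesterol synthesis genes. The response was thus not weaker in every list, but whether it was weaker in others was not tested. A weaker inflammatory response in that animal may account for the smaller acute-phase rise, and so may tissue handling. Immediate-early genes had deviations of 1.75, 1.12 and 0.18 in crizotinib replicates 1, 2 and 3. Neither account was tested. Deviations of genes from their mean level also went with gene length, at rank correlations of 0.151 and 0.157 in crizotinib replicates 1 and 2. The value was -0.178 in crizotinib replicate 3, and -0.0606, -0.0419 and -0.181 in control replicates 1, 2 and 3. The cause of this trend was not tested.

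Kupffer cell and T and NK cell markers were lower in all 3 crizotinib livers. Dilution by hepatocyte transcripts is argued against by cholangiocyte and B cell markers, with a median of 0.2221 (quartiles -0.0503 and 0.683), although stellate, sinusoidal endothelial and mesothelial markers, at -1.33, -1.34 and -2.61, go with it. Less blood is argued against by stellate cell markers, at most -1.154 in any crizotinib library, and for T and NK cells by B cell markers at 0.1536 (-0.35 to 0.46 with single libraries left out), although erythroid genes, at -1.70, and platelet markers, at -0.85 and below every control in all 3 crizotinib libraries, go with less blood. With GC and length offsets the Kupffer cell median was -2.578. Loss of these cells or lower expression within them after the drug may account for it; RNA of whole tissue does not part these, and neither was tested.

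Male-biased liver genes were lower. Reads shared between major urinary protein genes are argued against by the 20 members outside that family, all below 0 with a median of -2.815. Female animals in the crizotinib group are argued against by Y-linked genes, whose lowest ratio of crizotinib to control was 0.7781. Xist, the X-linked sex marker, goes the other way. It had 14.3, 14.4 and 6.93 CPM in crizotinib replicates 1, 2 and 3 against 0.199, 3.79 and 5.57 CPM in control replicates 1, 2 and 3 (edgeR adjusted p = 0.361). The cause of the Xist difference was not tested. With GC and length offsets the median was -3.049. A drug effect on hormone-driven liver transcription may account for it and was not tested.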
